A study of Homo sapiens with 4 samples.

How the data were processed

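Total RNA of untransfected Namalwa cells and of Namalwa lines stably transduced with a lentiviral vector for Oct-1A, Oct-1L or Oct-1X was amplified to biotin-labelled cRNA and hybridised to Illumina HumanHT-12 v4 BeadChips, per the labels' protocols. There were 4 arrays, 1 per group, and the file's own array count is 1 for each column. The design text says that RNA came from 4 cell lines for each condition, which can be read in more than 1 way, and the data show 1 array per group.

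The deposited probe table holds the mean bead intensity of each probe on a linear scale and without normalization per the file headers, with the standard error over beads, the number of beads and a detection p-value. The values, all above 0, show no background subtraction. How the detection p-value was computed is not given in the sources used here. The columns were matched to groups by their names. A second deposited table holds the authors' processed intensity values. Each of its columns equals the raw column times 1 constant (1.00923 for the control, 1.00363 for Oct-1A, 1.00923 for Oct-1L and 0.977914 for Oct-1X), so it is linear, uncentred and not background-corrected, and its method is not given in the sources used here. Its column medians were 141.292, 142.014, 143.613 and 132.018.

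Median raw signals were 140, 141.5, 142.3 and 135 on the control, Oct-1A, Oct-1L and Oct-1X arrays, and mean raw signals 394.7, 389.8, 363.3 and 414.3. The median bead standard error of detected probes was 5.37%, 5.57%, 5.67% and 5.00% of the signal. The 92 external spike-in probes were not detected on any array.

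Signals were corrected with limma 3.58.1 in R 4.3.3 by the normexp model, with the background inferred from the detection p-values, an offset of 16, quantile normalization over the 4 arrays and log2. A probe was taken as detected at a detection p-value under 0.01. Of 47309 probes, 43948 are RefSeq probes, 3268 UniGene probes and 93 controls, which were left out of all gene results. Symbols of RefSeq probes were updated through a RefSeq gene table of GRCh38.p14, used for names only: 35662 by Entrez identifier and 84 by accession, while 8202 kept the file's symbol, and 8836 received a new symbol. Probe coordinates are those of the file, and their genome build is not given in the sources used here. Each gene was read by the probe with the highest mean log2 signal over the 4 arrays. Of 33730 genes, 12283 were detected on at least 1 array and 8396 on all 4. Probes of 1 gene disagreed in sign for 14 of 196 called genes with several detected probes in the Oct-1A comparison, 15 of 203 in Oct-1L and 21 of 240 in Oct-1X, and between lines for 4 of 34 (Oct-1A against Oct-1L), 3 of 14 (Oct-1A against Oct-1X) and 14 of 72 (Oct-1L against Oct-1X).

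Each isoform line was compared with the control and with each other line, 6 comparisons in all, as log2 differences between 2 arrays. A call needed a 2-fold difference with both arrays detected, and genes detected on 1 array only were counted apart when their bound reached 2-fold. No test across genes was run, because each group has 1 array. The bead standard error of a difference had a median of 0.151 over detected genes and covers technical error within the arrays. Isoform arrays were normalized together with the control.

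Gene lists (28 lists with 1062 entries, of which 1034 matched a gene on the array) were fixed before the data were examined, as were the groups, the comparisons, the alternatives and the rule for named genes. The lists cover immunoglobulin chains, B cell receptor signalling, B cell transcription factors, POU family and cofactors, MHC class I and class II, interferon-stimulated genes, NF-kappaB and Epstein-Barr virus latency targets, chemokines and adhesion, mitosis, DNA replication, replication-dependent histones, small nuclear and polymerase III RNAs, ribosomal proteins, MYC targets, p53 targets, BCL2 family, oxidative stress, unfolded protein response, heat shock, glycolysis and hypoxia, oxidative phosphorylation, cholesterol and lipid synthesis and housekeeping genes, with markers of T and NK, myeloid, erythroid and platelet, and fibroblast and epithelial cells. Some genes are on more than 1 list. A list with at least 5 detected members is given by its median, a bootstrap standard error over genes (2000 draws) and the percentile of its median among 10000 random lists of the same size drawn from 20 bins of mean signal, which describes these arrays only. Where members were detected on 1 of the arrays, the median is also given with those members at their bound if its rounded value differs, and percentiles belong to the medians as measured.

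Named genes were the 8 largest called differences each way for each line against the control, the 4 brightest genes each way detected on 1 array only, the 5 largest each way for each pair of lines, the 10 largest each way called in all lines, up to 4 members per list, and POU2F1, POU2F2 and POU2AF1. Symbols that start with LOC, HS. or KIAA, pseudogenes of RPL and RPS genes and genes whose detected probes disagree in sign were left out of the largest and brightest genes. The list members and POU2F1, POU2F2 and POU2AF1 were named without this filter.

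The effect of the shared control array was estimated from 20 simulations of unchanged arrays, with noise of the spread among the isoform arrays or of the bead standard errors. The calls were tested on simulated data for the Oct-1A comparison (12114 genes tested). Changed genes were drawn from clearly detected genes read by 1 probe. Here genes detected on 1 array only also counted as called when their bound reached 2-fold. Of genes changed 1.5-fold, 1.49% were called, of those changed 2.5-fold 73.1%, of those changed 4-fold 90.9%, and of 11915 unchanged genes 0.227%. That rate holds for the noise of the simulated data, and with the larger spread among the isoform arrays 247 of 8396 genes simulated as unchanged were called per comparison. The spread among the isoform arrays also holds any difference between the isoform lines, so 247 is not a count from noise alone. In 200 simulated lists of 30 genes, 5.5% of unshifted lists fell outside percentiles 2.5 to 97.5, and 100% of lists shifted by 0.3. These lists were random genes of the simulated data, so the shares need not hold for lists of related genes or for the real arrays.

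Alternatives were no background correction, median scaling in place of quantile normalization, the authors' values, an offset of 50, a detection p-value of 0.05, no detection filter and the mean over detected probes. After the data were seen, the shared count without the Oct-1L array and the removal of the trend with probe position and GC content by loess (statsmodels 0.14.6, span 0.3) were added. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for all further steps.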

Results

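Namalwa is a human B cell line grown from a Burkitt lymphoma that carries Epstein-Barr virus. RNA of untransfected Namalwa cells (the control) and of 3 lines stably transduced with FLAG-tagged N-terminal isoforms of Oct-1 (Oct-1A, Oct-1L or Oct-1X) was hybridised to Illumina HumanHT-12 v4 BeadChips. Oct-1 is the POU-domain transcription factor encoded by POU2F1, and the series asks whether its isoforms control distinct sets of genes. Each of the 4 groups had 1 array, so the number of arrays limits the precision, no difference given here has a replicate check and no p-value is given. The control cells were untransfected and no empty-vector line was measured, while the transduced cells were selected and kept with blasticidin. Of 47309 probes, 12736 were detected on the control array, 11870 on the Oct-1A array, 11975 on the Oct-1L array and 13051 on the Oct-1X array, with a median of 21 to 22 beads behind each signal. Differences are log2 differences of normalized signal, and the number after each ± is the bead standard error of the difference, which covers technical error within the arrays only. A gene is called higher or lower where the difference is at least 2-fold and both arrays detected it. A gene detected on 1 of the arrays compared has only a bound, given as "at least N-fold", from the higher of the lowest detected signal of the dim array and the dim probe's own value.

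POU2F1 was read by 1 probe, on chromosome 1 from 165651657 to 165651706 in the file's coordinates, whose genome build is not given in the sources used here. The raw signal was 173.6 on the control array, 161.7 on the Oct-1A array, 185.0 on the Oct-1L array and 217.3 on the Oct-1X array, with detection p-values of 0.00909, 0.06234, 0.00649 and 0. It was not detected on the Oct-1A array, and no fold is given there because the control's signal lies below the lowest detected signal of that array. The normalized signal differed from the control by 0.20 ± 0.27 and 0.70 ± 0.26 for Oct-1L and Oct-1X. The probe sequence reads 4 codons and the stop codon TGA in its first 15 bases, and its other 35 bases lie after the stop, in the 3' UTR. Most of the probe therefore lies outside a coding-sequence transgene, and its signal does not check the transgene's level or the labels. POU2F2, which encodes the related factor Oct-2, was not detected on the Oct-1A array, at least 1.63-fold lower than the control, and differed by -0.49 ± 0.36 and -0.47 ± 0.32 on the Oct-1L and Oct-1X arrays. POU2AF1, the B cell coactivator of Oct-1 and Oct-2, differed by -0.44 ± 0.11, -0.87 ± 0.12 and -0.22 ± 0.10 for Oct-1A, Oct-1L and Oct-1X. Over 20 or 21 detected members, the list of POU family genes and cofactors had medians of -0.08 (0 with members detected on 1 array at their bound), 0.07 and -0.17, with no member called.

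The comparison of Oct-1A with the control asks which genes differ in cells that carry the Oct-1A isoform. Mitosis genes had the highest list median of the Oct-1A line, and NF-kappaB and Epstein-Barr virus latency targets the lowest. Of 44 detected genes of mitosis, 30 were called higher and none lower, with a median difference of 1.36 (1.33 with bounds), above all 10000 random lists matched on signal. CDCA3, a trigger of mitotic entry, was higher by 2.15 ± 0.25 (4.44-fold, probe on chromosome 12 from 6828529 to 6828578), CENPA, the centromeric histone H3 variant, was 4.01-fold higher, and CDC20, an activator of the anaphase-promoting complex, was higher by 1.97 ± 0.14. The spindle gene PSRC1 was at least 4.53-fold higher and the chromokinesin KIF4A at least 3.86-fold higher. The largest differences among called genes also included UBASH3B (2.04 ± 0.20), PHACTR1 (2.02 ± 0.20), FOXN4 (2.03 ± 0.20), the small Cajal body RNA SCARNA14 (2.02 ± 0.34) and the cyclophilin pseudogene PPIAP78 (2.04 ± 0.26). ADARB1, which encodes an RNA-editing deaminase, was at least 6.18-fold higher, and the growth factor gene HBEGF at least 3.43-fold higher.

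DNA replication genes had a median of 0.68 in the Oct-1A line, with 13 of 44 called higher and none lower. These included POLA1 (1.46 ± 0.23), which encodes the catalytic subunit of DNA polymerase alpha, the helicase gene MCM2 (1.45 ± 0.17) and the thymidylate synthase gene TYMS (1.32 ± 0.13). MYC targets and ribosome biogenesis genes had a median of 0.62 (0.58 with bounds) and 3 of 34 called higher, among them ODC1 (1.63 ± 0.07), the first enzyme of polyamine synthesis, and CAD (1.05 ± 0.15) of pyrimidine synthesis. Both medians lay above all 10000 random lists.

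Lower in the Oct-1A line were LPP (-3.45 ± 0.09, 10.9-fold lower, probe on chromosome 3 from 190079051 to 190079100), which encodes a focal adhesion protein, and the chitinase-like gene CHI3L2 (-3.41 ± 0.20). They were followed by the kinase inhibitor gene CAMK2N1 (-2.93 ± 0.23), TMEM154 (-2.76 ± 0.24), the phosphatase gene DUSP5 (-2.73 ± 0.19), MIR155HG (-2.69 ± 0.13), the host transcript of miR-155, SRL (-2.66 ± 0.25) and JSRP1 (-2.66 ± 0.16). INHBE, which encodes an inhibin subunit, was at least 14.0-fold lower, the kinase gene ALPK2 at least 12.5-fold, the interferon-induced gene IFITM1 at least 10.5-fold and the chemokine receptor gene ACKR3 at least 7.94-fold. Among 30 detected NF-kappaB and Epstein-Barr virus latency targets, 10 were called lower and none higher, with a median of -1.16, or -0.74 with the 9 members detected on 1 array at their bound. The chemokine receptor gene CCR7 was lower by -2.25 ± 0.23, FCER2 (CD23) by -2.22 ± 0.19 and CD83 by -2.08 ± 0.15, and the cytokine subunit gene EBI3 was at least 3.60-fold lower. Interferon-stimulated genes had a median of -0.83 (-0.53 with bounds) and 8 of 37 called lower, including the guanylate-binding protein gene GBP2 (-2.29 ± 0.21) and ISG15 (-1.89 ± 0.14). Genes of the unfolded protein and amino acid responses had a median of -0.62 and 8 of 38 called lower, including WARS1 (-2.20 ± 0.13), a tryptophanyl-tRNA synthetase, and PSAT1 (-2.05 ± 0.10) of serine synthesis. All 3 medians as measured lay below all 10000 random lists.

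In total 617 genes were called in the Oct-1A line, 275 higher and 342 lower, among 8872 genes detected on both arrays. Simulated unchanged arrays with the spread seen among the isoform arrays gave 247 called genes per comparison with the control, among the 8396 genes detected on all 4 arrays. That spread also holds any difference between the isoform lines. In the Oct-1A line a further 33 higher and 103 lower genes were detected on 1 array only with a bound of at least 2-fold. The count of called genes was 257 (88 higher and 169 lower) from the authors' values, 259 without background correction and 993 without a detection filter.

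In the Oct-1L line, mitosis genes likewise had the highest list median and NF-kappaB and latency targets the lowest, and the medians of small nuclear RNAs and oxidative phosphorylation genes lay below 0. Of 44 mitosis genes, 31 were called higher and none lower, with a median of 1.50, or 1.48 with bounds. CDC20 was higher by 2.21 ± 0.13, CENPA by 2.21 ± 0.17, the kinesin gene KIF20A by 2.17 ± 0.18, CDCA3 by 2.13 ± 0.25, the mitotic kinase gene PBK by 2.10 ± 0.13 and SGO2, which protects centromeric cohesion, by 2.21 ± 0.38. Also higher were RGS13 (2.18 ± 0.17), a regulator of G-protein signalling in germinal centre B cells, and TMPO (1.95 ± 0.23), which encodes a nuclear lamina protein. PSRC1 was at least 5.28-fold higher, KIF4A at least 3.08-fold, the ribosome biogenesis gene RRP15 at least 3.29-fold and the nuclease-helicase gene DNA2 at least 3.02-fold. DNA replication genes had a median of 0.68 (8 of 44 called higher) and MYC targets and ribosome biogenesis genes 0.63 (4 of 33), with MYC itself higher by 1.41 ± 0.13.

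The largest differences among called lower genes of the Oct-1L line were IFITM1 (-3.18 ± 0.28, 9.08-fold lower), CHI3L2 (-3.07 ± 0.24), the adaptor gene LAT2 (-2.87 ± 0.15), DNASE2 (-2.76 ± 0.23), a lysosomal nuclease gene, the cation channel gene TRPM4 (-2.72 ± 0.11), WARS1 (-2.71 ± 0.10), DUSP5 (-2.65 ± 0.17) and PPP1R15A (-2.55 ± 0.19), which encodes the stress-induced phosphatase subunit GADD34. INHBE was at least 14.1-fold lower, ALPK2 at least 12.6-fold, the Fc receptor gamma chain gene FCER1G at least 9.33-fold and the IgM receptor gene FCMR at least 7.55-fold. NF-kappaB and latency targets had a median of -1.22 (-1.02 with the 11 members detected on 1 array at their bound) and 10 of 30 called lower, with FCER2 at least 6.49-fold and CCR7 at least 5.83-fold lower. Interferon-stimulated genes had a median of -0.79 (-0.74 with bounds, 9 of 37 called lower) and unfolded protein response genes -0.71 (10 of 38), including the transcription factor gene ATF5 (-2.11 ± 0.17).

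Antigen presentation genes had lower values in the Oct-1L line. MHC class I genes had a median of -0.91, or -0.68 with bounds, and 5 of 19 were called lower, led by HLA-E (-2.12 ± 0.14). MHC class II genes had a median of -0.84 and 5 of 17 called lower, led by HLA-DQA1 (-2.10 ± 0.16), HLA-DRB4 (-1.40 ± 0.18) and HLA-DRB1 (-1.26 ± 0.12). Class I genes, and the DRB genes, are close in sequence, so a probe may read more than 1 of them and the assignment to single genes is uncertain. Small nuclear and polymerase III RNAs had a median of -0.96 and 6 of 15 called lower, including the spliceosomal RNU1-1 (-1.58 ± 0.14), and RNU4-2 was at least 4.52-fold lower. The called RNU1-1, RNU1-3 (-1.20), RNVU1-18 (-1.09) and RNU1-28P (-1.30) are by name copies or variants of the U1 RNA, so their calls may not be independent. Oxidative phosphorylation genes had a median of -0.23, at percentile 0.05 of the random lists, and 2 of 61 were called lower, NDUFA3 (-1.33 ± 0.15) of complex I and ATP5ME (-1.31 ± 0.09) of the ATP synthase. Among genes outside these groups, those with a probe ending within 500 bases of the transcript start had a median of -0.13 on this array against the control, and those with a probe beyond 2000 bases 0.05.

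In total 685 genes were called in the Oct-1L line, 286 higher and 399 lower, among 8932 detected on both arrays. Another 33 higher and 89 lower genes were detected on 1 array only with a bound of at least 2-fold. The count was 289 (70 higher and 219 lower) from the authors' values and 299 (103 higher and 196 lower) without background correction.

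The Oct-1X line had the same main groups, with more genes called and with ribosomal RNA and NBPF probes lower. Of 44 mitosis genes, 34 were called higher and none lower, with a median of 1.49, or 1.38 with bounds. CDCA3 was higher by 2.40 ± 0.25 (5.28-fold), the spindle gene DLGAP5 by 2.26 ± 0.24, CENPA by 2.12 ± 0.16 and the mitotic kinase gene AURKB by 2.09 ± 0.13, and KIF4A was at least 6.23-fold higher. DNA replication genes had a median of 0.71 (14 of 44 called higher), with the thymidine kinase gene TK1 at 1.78 ± 0.15, and MYC targets and ribosome biogenesis genes 0.61, or 0.59 with bounds (3 of 36). The small Cajal body RNAs SCARNA14 (2.72 ± 0.30), SCARNA18 (2.37 ± 0.19) and SCARNA8 (2.09 ± 0.18) and UBASH3B (2.20 ± 0.17) were among the largest differences. SNORA27 was at least 4.28-fold, RRP15 at least 4.45-fold and the actin-binding protein gene ABLIM1 at least 4.69-fold higher.

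Lower in the Oct-1X line were the probes named NBPF9 (-4.07 ± 0.21, 16.8-fold lower, on chromosome 1 from 146620225 to 146620274), NBPF10 (-3.62 ± 0.13) and NBPF8 (-3.36 ± 0.21), members of 1 family of near-identical gene copies whose probes are uncertain between copies. INHBE (-3.85 ± 0.26), CHI3L2 (-3.44 ± 0.17), TMEM154 (-3.27 ± 0.21), CAMK2N1 (-3.24 ± 0.18) and JSRP1 (-3.15 ± 0.26) followed. ALPK2 was at least 14.0-fold, IFITM1 at least 11.7-fold, ACKR3 at least 8.87-fold and the tetraspanin gene TSPAN8 at least 8.14-fold lower. NF-kappaB and latency targets had a median of -1.06 (-0.66 with 9 members at their bound) and 10 of 30 called lower, including CCR7 (-2.65 ± 0.12) and FCER2 (-2.51 ± 0.18). Interferon-stimulated genes had a median of -0.89 (-0.70 with bounds, 10 of 38 called lower), including GBP2 (-3.04 ± 0.21) and the regulator gene IRF7 (-2.30 ± 0.12). Unfolded protein and amino acid response genes had a median of -0.80 and 13 of 38 called lower, including ATF5 (-2.55 ± 0.19) and the asparagine synthetase gene ASNS (-2.15 ± 0.10). Glycolysis and hypoxia genes had a median of -0.49 (-0.39 with bounds) and 7 of 34 called lower, led by PFKFB4 (-2.76 ± 0.15), which sets fructose 2,6-bisphosphate levels, and the aldolase gene ALDOC (-2.38 ± 0.09). Cholesterol and lipid synthesis genes had a median of -0.69 and 8 of 28 called lower, led by INSIG1 (-2.26 ± 0.12), a feedback regulator of sterol synthesis, and the sterol oxidase gene MSMO1 (3.99-fold lower). The Oct-1X array gave lower signal at 5' probes: for 574 transcripts read by 2 probes, the difference of the control from it was larger at the 5' than at the 3' probe by a median of 0.15 (95% bootstrap interval 0.12 to 0.19), a measure that was 0.00 for Oct-1A and -0.02 for Oct-1L.

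In total 805 genes were called in the Oct-1X line, 356 higher and 449 lower, among 9223 detected on both arrays. There 60 higher and 99 lower genes were detected on 1 array only with a bound of at least 2-fold. The count was 418 (221 higher and 197 lower, a majority in the other direction) from the authors' values and 365 (135 higher and 230 lower) without background correction.

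**Figure D1:**
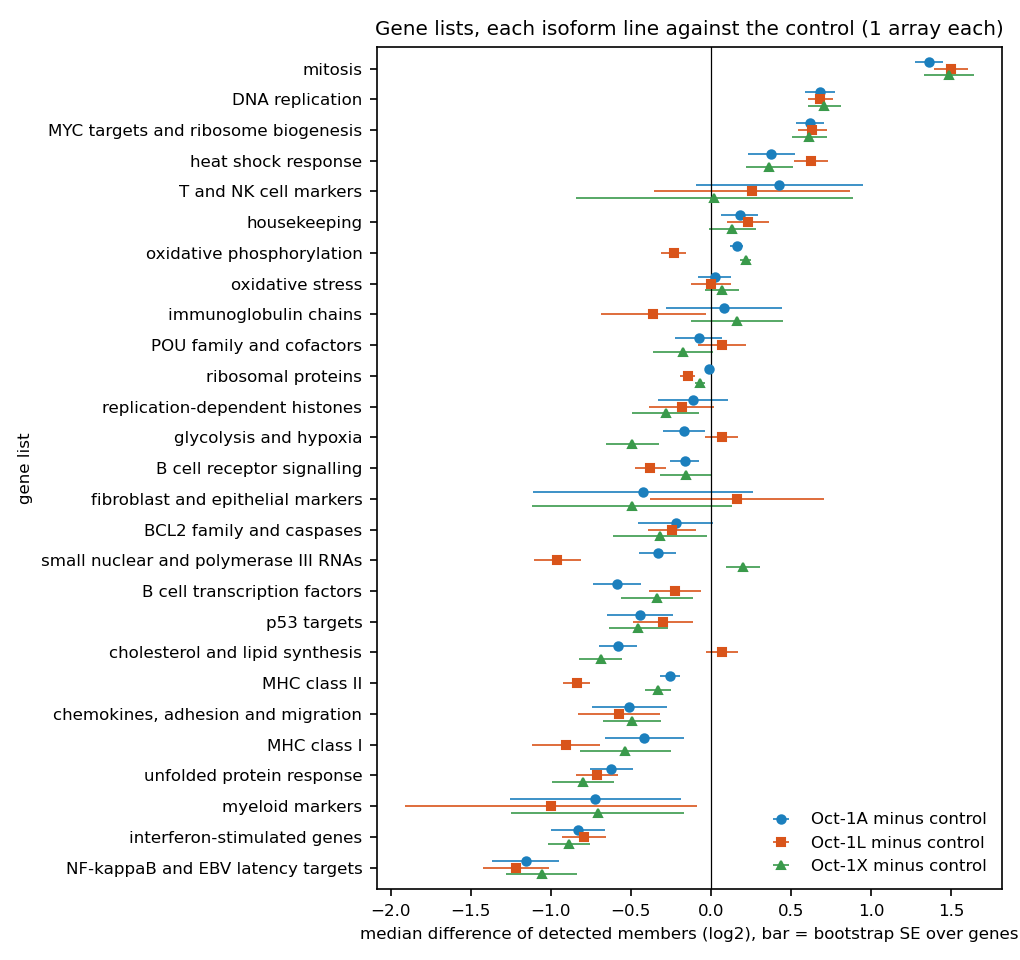
Median log2 difference from the control of the detected members of each gene list with at least 5 members, for the Oct-1A (circles), Oct-1L (squares) and Oct-1X (triangles) lines, with bars of 1 bootstrap standard error over genes and 1 array per line. The mitosis list lies at 1.36 to 1.50 and the NF-kappaB and latency list at -1.06 to -1.22, while the small nuclear RNA list spans -0.96 (Oct-1L) to 0.20 (Oct-1X).

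For Oct-1A, Oct-1L and Oct-1X in turn, heat shock genes had medians of 0.38, 0.62 and 0.37 (percentiles 99.9, 100 and 99.6), with HSPA6 lower by -1.42 ± 0.22, -1.54 ± 0.14 and -1.76 ± 0.15 against the list's direction. MHC class I genes of the Oct-1A and Oct-1X lines had medians of -0.42 (7 of 19 called lower) and -0.53 (7 of 20), and MHC class II genes -0.25 and -0.33 (2 of 17 in each). B cell transcription factor genes had medians of -0.59, -0.23 and -0.34 (-0.44, -0.18 and -0.30 with bounds), with 4, 3 and 6 of 28 called lower. LMO2, a germinal centre factor, was at least 7.45-fold lower in the Oct-1A line, at least 7.54-fold in the Oct-1L line and lower by -2.97 ± 0.28 in the Oct-1X line. B cell receptor signalling genes had medians of -0.16, -0.38 (below all random lists) and -0.16, with 3 of 33, 5 of 31 and 5 of 32 called lower, led by the complement receptor gene CR2 (-2.60 ± 0.27, -2.11 ± 0.25 and -1.98 ± 0.14). Chemokine, adhesion and migration genes had medians of -0.51, -0.57 and -0.49 (-0.40, -0.57 and -0.45 with bounds) and 5, 7 and 5 of 26 called lower, with the integrin gene ITGB7 lower by -2.35 ± 0.20, -2.09 ± 0.22 and -2.09 ± 0.16. Targets of p53 had medians of -0.44, -0.30 and -0.45 (-0.37, -0.13 and -0.39 with bounds), with the cell cycle inhibitor gene CDKN1A lower by -1.55 ± 0.08, -1.18 ± 0.11 and -1.51 ± 0.08. BCL2 family and caspase genes had medians of -0.22, -0.24 and -0.32 (-0.12, -0.20 and -0.26 with bounds), and replication-dependent histone genes -0.11, -0.18 and -0.28 (-0.08, -0.12 and -0.26 with bounds). Cholesterol and lipid synthesis genes of the Oct-1A and Oct-1L lines had medians of -0.58 (6 of 28 called lower, below all random lists) and 0.07 (2 of 29), glycolysis and hypoxia genes -0.17 (-0.145 with bounds) and 0.07, and oxidative phosphorylation genes of the Oct-1A and Oct-1X lines 0.16 and 0.22. Small nuclear and polymerase III RNAs had medians of -0.33 in the Oct-1A and 0.20 (0.14 with bounds) in the Oct-1X line. Ribosomal protein genes had medians of -0.01, -0.15 and -0.07, oxidative stress genes 0.02, -0.00 and 0.07, and housekeeping genes 0.18, 0.23 and 0.13.

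Of 25 entries of the immunoglobulin list, 5 were matched and detected, JCHAIN, IGLL1, IGLL3P, VPREB1 and VPREB3, with medians of 0.08, -0.36 and 0.16. None of these is an antibody heavy, kappa or lambda chain gene, so the values do not stand for immunoglobulin genes. Markers of other cell types were few: T and NK cell markers (7, 6 and 5 detected) had medians of 0.43, 0.25 and 0.02 (0.22, 0.18 and 0.02 with bounds), and fibroblast and epithelial markers (5 detected) -0.42, 0.16 and -0.50 (-0.01, 0.16 and -0.17 with bounds). Myeloid markers (8, 7 and 7 detected) had medians of -0.72 (-0.61 with bounds), -0.997 and -0.71. Among them the cystatin gene CST3 was lower by -2.05 ± 0.18, -1.95 ± 0.13 and -1.77 ± 0.13. AIF1 was at least 4.41-fold lower in the Oct-1L line. Of the erythroid and platelet markers, PPBP was at least 2.64-fold higher in the Oct-1A line, and AHSP at least 1.30-fold higher. PPBP was at least 1.38-fold higher in the Oct-1L line and at least 1.81-fold in the Oct-1X line, where AHSP was at least 1.14-fold higher.

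The comparison across lines asks how far the isoforms act on shared genes. Called in the same direction in all 3 lines were 275 genes, 116 higher and 159 lower. A gene has to be detected on every array to be among them, so INHBE, ALPK2 and IFITM1 are not. By mean difference the first 10 higher genes were CDCA3, CENPA, CDC20, DLGAP5, KIF20A, the cyclin genes CCNB1 and CCNB2, FOXN4, the kinetochore gene CENPF and PBK. CCNB1 differed by 1.93 ± 0.21, 1.87 ± 0.22 and 1.87 ± 0.20 in the Oct-1A, Oct-1L and Oct-1X lines, CCNB2 by 1.83 ± 0.13, 1.84 ± 0.14 and 1.95 ± 0.12, and CENPF by 1.73 ± 0.15, 1.69 ± 0.21 and 2.01 ± 0.13. The first 10 lower genes were CHI3L2, LPP, JSRP1, DUSP5, TMEM154, DNASE2, CAMK2N1, DBNDD1, GSTA4 and MIR155HG. DBNDD1 differed by -2.60 ± 0.10, -2.11 ± 0.11 and -2.79 ± 0.16, the glutathione transferase gene GSTA4 by -2.51 ± 0.19, -1.96 ± 0.18 and -2.93 ± 0.25, and MIR155HG by -2.69 ± 0.13, -1.74 ± 0.16 and -2.77 ± 0.12. With the other arrays taken in turn as the common reference, 3 genes (Oct-1A), 46 genes (Oct-1L) and 31 genes (Oct-1X) were called in the same direction on all 3 remaining arrays.

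**Figure D2:**
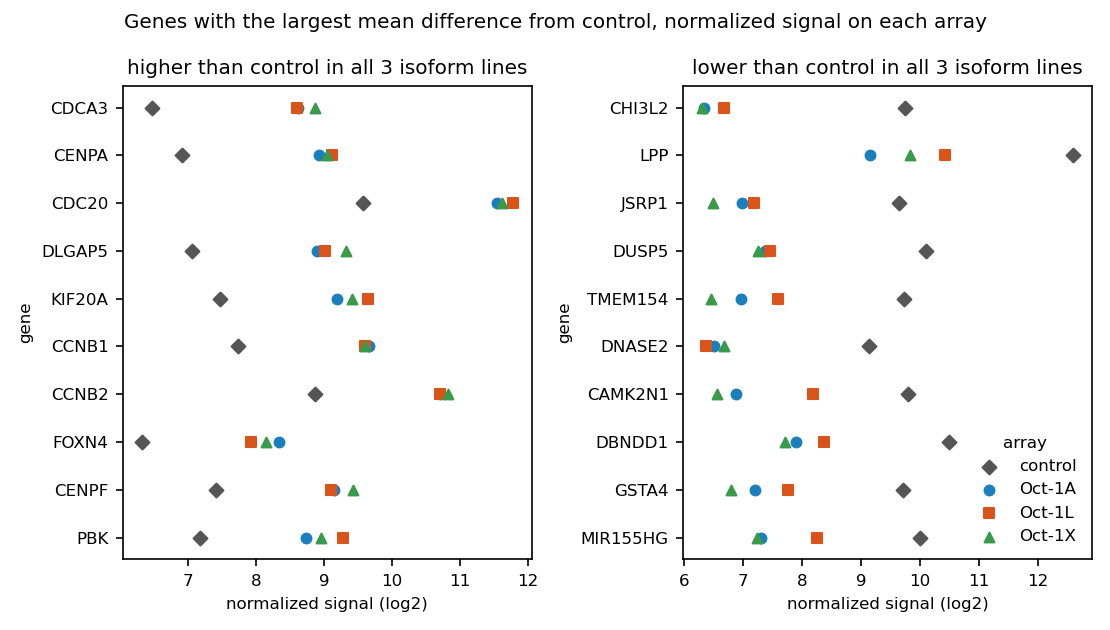
Normalized signal (log2) on each of the 4 arrays for the 10 genes with the largest mean difference among those called higher (left) and lower (right) in all 3 isoform lines; each point is 1 array. The control (diamonds) lies at least 2-fold from each isoform array for all 20 genes.

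The comparisons share the control array, which alone makes them resemble each other. Simulated unchanged arrays with the spread seen among the isoform arrays gave 19.4 shared higher and 20.9 shared lower genes, a correlation of differences of 0.50 and a covariance of 0.079. That spread also holds any difference between the isoform lines, so these values are not those of noise alone. Across 8396 genes detected on all arrays, which are not independent replicates, the observed correlations were 0.75 (Oct-1A and Oct-1L), 0.87 (Oct-1A and Oct-1X) and 0.69 (Oct-1L and Oct-1X), with covariances of 0.240, 0.304 and 0.248. Called in the same direction were 140 higher and 182 lower genes for Oct-1A and Oct-1L, 204 and 255 for Oct-1A and Oct-1X, and 150 and 193 for Oct-1L and Oct-1X, against 79.4 genes of both directions together in a pair of the simulated unchanged lines. With 1 control array the control cannot be split, so part of the excess may come from the shared control. From the authors' values 123 genes were shared (34 higher and 89 lower), without background correction 130 (40 and 90), without a detection filter 442, and without the Oct-1L array 459.

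A call needs both arrays detected, so a gene lost below detection in the other lines counts here as called in 1 line only. IFITM1 (called lower in the Oct-1L line) and INHBE (called lower in the Oct-1X line) are such genes. Of the genes called lower in 1 line and in no other, 59 of 64 (Oct-1A), 147 of 183 (Oct-1L) and 132 of 160 (Oct-1X) had the same sign in both other lines. Of those called higher it was 45 of 47, 106 of 112 and 103 of 118. The shared control alone gave the same sign for 60.9% of such calls in the simulated unchanged arrays with the isoform spread, and for 88.9% with bead noise, where few were called. A gene with such a call that was also at least 2-fold from both other isoform lines was found 3 times in the Oct-1A line and 44 times in the Oct-1L line, all lower. In the Oct-1X line it was 2 times higher and 23 times lower. The 44 of the Oct-1L line include pseudogenes of RPL and RPS genes, snoRNAs and respiratory chain genes. The Oct-1L array was lower for genes with a probe ending within 500 bases of the transcript start. The 3 of Oct-1A were MYBL1 (-1.59 ± 0.30), a germinal centre transcription factor gene, OSBPL10 and the predicted transcript LOC649210. The 2 higher of Oct-1X were STK11IP (1.07) and again LOC649210 (3.48), which is called in both lines, in opposite directions. These genes, apart from MYBL1, were picked for naming here after their values were seen.

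The lines were then compared with each other, which needs no control array. Oct-1A and Oct-1L differed in 187 called genes, 121 higher and 66 lower in Oct-1A, among 8773 detected on both arrays. Higher in Oct-1A were ADARB1 (2.51 ± 0.22), PPP6R1 (1.80 ± 0.21), PHACTR1 (1.76 ± 0.21) and the short RNAs SNORD104 (1.81 ± 0.21) and SCARNA13 (1.78 ± 0.14). Lower in Oct-1A were the Rac GTPase-activating protein gene CHN2 (-2.25 ± 0.24), ARLN (-1.62 ± 0.15), the CDK inhibitor gene CDKN2C (-1.59 ± 0.21), MYBL1 (-1.45 ± 0.27) and RGS16 (-1.43 ± 0.16). BCL6, the germinal centre repressor, was lower by -1.25 ± 0.12. Above all 10000 random lists lay MHC class II genes (0.57, 3 of 17 called higher, led by HLA-DRB1 at 1.33 ± 0.12), oxidative phosphorylation genes (0.42, 5 of 62, led by ATP5ME at 1.42 ± 0.10) and small nuclear and polymerase III RNAs (0.74, with the 5S RNA gene RNA5S9 at 1.36 ± 0.19). Below all random lists lay cholesterol and lipid synthesis genes (-0.52, or -0.46 with bounds, 4 of 29 called lower, including INSIG1 at -1.21 ± 0.13) and glycolysis and hypoxia genes (-0.36, none called). The 5 genes of the immunoglobulin list had a median of 0.81 (percentile 99.97). After a trend with probe position and GC content was removed, the medians were 0.52 (MHC class II), 0.22 (oxidative phosphorylation), 0.59 (small nuclear RNAs), -0.40 (cholesterol), -0.31 (glycolysis) and 0.51 (the immunoglobulin list). The count was 79 (67 higher and 12 lower) from the authors' values, 65 without background correction and 379 without a detection filter. With the trend over probe position and GC content removed it was 131 (75 higher and 56 lower).

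Oct-1A and Oct-1X were the closest pair, with 55 called genes, 40 higher and 15 lower in Oct-1A, among 9099 detected on both arrays. Higher in Oct-1A were the 28S ribosomal RNA probe RNA28SN5 (2.73 ± 0.10), NBPF9 (2.47 ± 0.23), NBPF10 (2.08 ± 0.15), NBPF8 (1.90 ± 0.21) and PFKFB4 (1.85 ± 0.15). Lower in Oct-1A were the cytokine gene LTB (-1.69 ± 0.11), the oxysterol-binding protein gene OSBPL10 (-1.36 ± 0.17), CDC42SE1 (-1.28 ± 0.23), MYBL1 (-1.22 ± 0.27) and OTUD6B (-1.21 ± 0.17). Glycolysis and hypoxia genes had a median of 0.23, above all random lists, with PFKFB4, ALDOC (1.57 ± 0.12) and DDIT4 (1.10 ± 0.18) called, and small nuclear and polymerase III RNAs -0.51 (-0.42 with bounds) with none called. Mitosis genes had a median of -0.16 (percentile 0.05), and B cell transcription factor genes -0.225, or -0.21 with bounds (percentile 0.02). With the trend over probe position and GC content removed, the medians were 0.28 (glycolysis), -0.57 (small nuclear RNAs), -0.14 (mitosis) and -0.15 (B cell transcription factors). At 5' probes the Oct-1X array was lower than the mean of the other isoform arrays, by a median of 0.16 more than at 3' probes (95% bootstrap interval 0.13 to 0.20). The count of called genes was 19 from the authors' values, 20 (18 higher and 2 lower) without background correction, 33 (28 and 5) with offset 50 and 157 without a detection filter.

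Oct-1L and Oct-1X were the most distant pair, with 354 called genes, 163 higher and 191 lower in Oct-1L, among 9038 detected on both arrays. Higher in Oct-1L were NBPF9 (3.72 ± 0.22), NBPF10 (3.21 ± 0.14), NBPF8 (3.07 ± 0.21), RNA28SN5 (3.07 ± 0.10) and PFKFB4 (2.52 ± 0.16). Lower in Oct-1L were SCARNA11 (-2.07 ± 0.14), PTPN6 (-1.98 ± 0.15), which encodes the inhibitory phosphatase SHP-1, ADARB1 (-1.94 ± 0.22), CRIP1 (-1.94 ± 0.18) and SNORA12 (-1.91 ± 0.13). Glycolysis and hypoxia genes (0.59, or 0.57 with bounds, 7 of 33 called higher, led by PFKFB4 and ALDOC at 2.09 ± 0.11) and cholesterol and lipid synthesis genes (0.55, or 0.54 with bounds, 5 of 29, led by INSIG1 at 2.18 ± 0.10) lay above all random lists. Oxidative phosphorylation genes (-0.39, or -0.38 with bounds, 4 of 62 called lower, led by NDUFA3 at -1.77 ± 0.15) and small nuclear and polymerase III RNAs (-1.15, or -1.13 with bounds, 8 of 16, including RNU1-1 at -1.43 ± 0.13) lay below all of them. Several of the small nuclear RNAs are by name copies of U1 or U6, so their calls may not be independent. MHC class II genes had a median of -0.49 (percentile 0.01). The 5 genes of the immunoglobulin list had a median of -0.78 (percentile 0.135). Of these VPREB3 (-1.54 ± 0.18) and VPREB1 (-1.14 ± 0.08), parts of the surrogate light chain system, were lower in Oct-1L. After a trend with probe position and GC content was removed, the medians were 0.53 (glycolysis), 0.60 (cholesterol), -0.24 (oxidative phosphorylation), -1.11 (small nuclear RNAs), -0.44 (MHC class II) and -0.57 (the immunoglobulin list). The Oct-1X array was lower at 5' probes, as given for Oct-1A against Oct-1X. Outside the oxidative phosphorylation and small RNA groups, the Oct-1L array was lower than the mean of the other isoform arrays by a median of -0.16 for 1449 genes whose probe ends within 500 bases of the transcript start, and higher by 0.04 for 4982 genes with a probe beyond 2000 bases. The count was 212 (44 higher and 168 lower) from the authors' values, 125 without background correction, 230 with offset 50 and 586 without a detection filter. With the trend over probe position and GC content removed it was 317 (181 higher and 136 lower).

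Of the other lists, interferon-stimulated genes had medians of 0.22 (0.16 with bounds) for Oct-1A against Oct-1L and 0.16 against Oct-1X, at percentiles 99.3 and 99.8, with none called. Ribosomal protein genes had medians of 0.11 (Oct-1A against Oct-1L), 0.04 (Oct-1A against Oct-1X) and -0.12 (Oct-1L against Oct-1X), at percentiles 99.8, 98.2 and 0.17. With the trend over probe position and GC content removed, the medians with Oct-1L changed sign, to -0.052 and 0.035 (percentiles 78.1 and 15.5), and the other was 0.01 (percentile 78.1). Against Oct-1L, Oct-1A had unfolded protein response genes at 0.16 (percentile 99.0) and p53 targets at -0.22 (percentile 1.84), which became 0.23 and -0.06 (percentile 25.1) with the trend removed. Against Oct-1X, it had cholesterol and lipid synthesis genes at 0.15 (percentile 99.7) and MHC class II genes at 0.13 (percentile 97.8), and 0.19 (percentile 99.8) and 0.10 (percentile 90.2) with the trend removed. From the authors' values the first of these was -0.00164. All other list medians between lines lay at percentiles of 2.53 to 96.7.

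**Figure D3:**
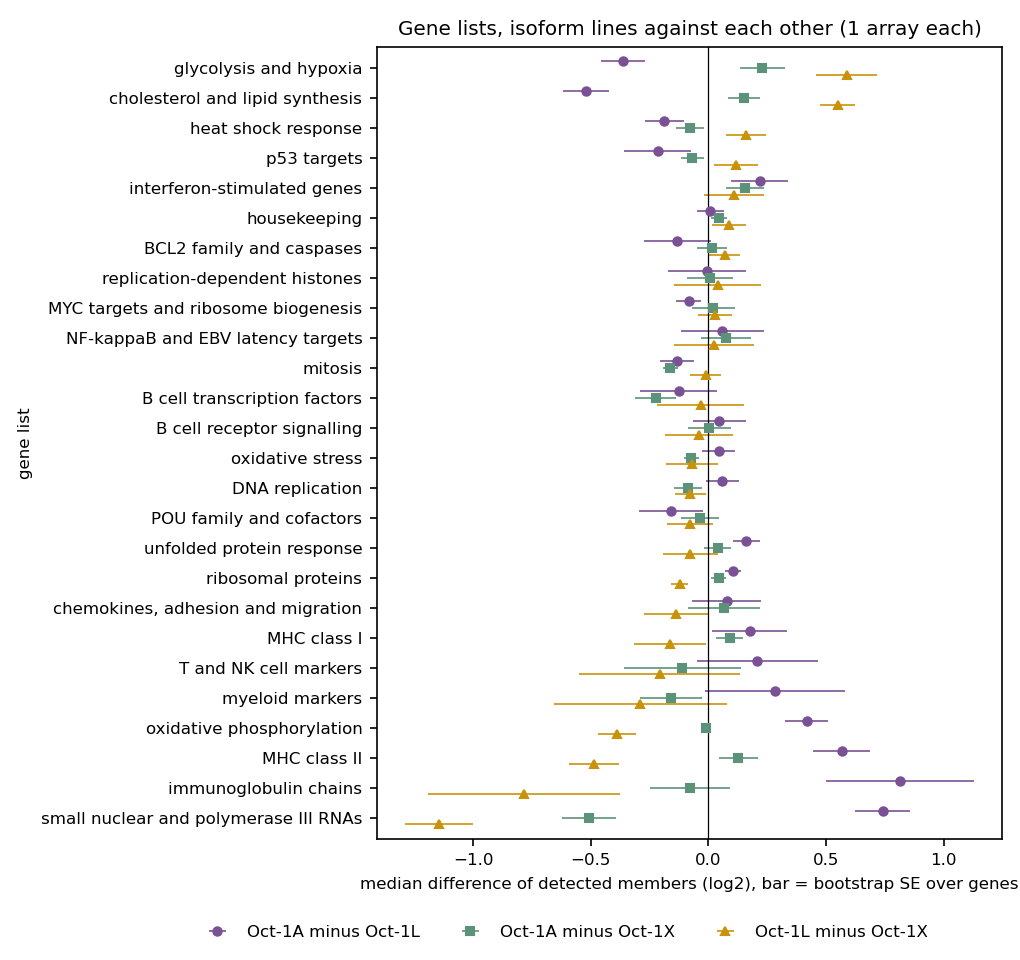
Median log2 difference between isoform lines of the detected members of each gene list with at least 5 members, for Oct-1A minus Oct-1L (circles), Oct-1A minus Oct-1X (squares) and Oct-1L minus Oct-1X (triangles), with bars of 1 bootstrap standard error over genes and 1 array per line. The 2 comparisons with Oct-1L lie on opposite sides of 0 for small nuclear RNAs (0.74 and -1.15), MHC class II (0.57 and -0.49) and oxidative phosphorylation (0.42 and -0.39), where Oct-1A minus Oct-1X lies at -0.51, 0.13 and -0.01.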

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

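The tests of raw brightness, growth state, snRNA-type promoters (both groups), short RNA loss for small nuclear RNAs, probe position and ribosomal RNA in the paragraphs that follow were chosen after the result they concern was seen, and the wording for NBPF probes and the cut on bright small RNAs were also settled then.

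LOC649210, a predicted transcript similar to an immunoglobulin lambda variable region, stood out because its calls against the control went in opposite directions, lower in the Oct-1A line (-1.14) and higher in the Oct-1X line (3.48). Its raw signals were 291.1 on the control, 189.8 on the Oct-1A, 332.3 on the Oct-1L and 2450.6 on the Oct-1X array, and the difference of Oct-1A from Oct-1X was -4.63, which was not tested, since each line has 1 array.

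The control array stood apart from the 3 isoform arrays, with 275 genes called in the same direction in all lines and mitosis genes higher in each of them. A brighter or dimmer control array does not account for it, because its mean raw signal of 394.73 lay inside the range of the isoform arrays (363.28 to 414.26). More degraded RNA in the control sample is argued against by a 5' minus 3' probe shift of -0.0396 (95% bootstrap interval -0.080 to -0.015, 574 transcripts), where a shift above 0.1 was set as the sign of degradation. The isoform mean behind this shift includes the Oct-1X array, itself lower at 5' probes. Taken as control minus each line, where degradation of the control would give negative values, the shift was 0.00 (Oct-1A), -0.02 (Oct-1L) and 0.15 (Oct-1X). The growth state of the control culture, or selection and transduction of the other lines, may account for the control array standing apart. Neither can be told apart from an effect common to the isoforms. The lowest of the mitosis medians was 1.36, and the design has 1 untransfected array and no empty-vector line to set it against.

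The Oct-1L array was lower than the other isoform arrays for genes with a probe ending within 500 bases of the transcript start. The small nuclear RNA and oxidative phosphorylation lists both had lower medians on it. Neither a trend with probe GC content nor one with probe position, as fitted, accounts for all of the difference of these lists. The median of 78 members was -0.49 ± 0.09 (bootstrap SE) as measured, -0.46 ± 0.08 with the first and -0.37 ± 0.08 with the other removed. The position trend was a smooth loess (span 0.3) that did not use transcript length, so a further effect of length stays open. The small nuclear and polymerase III RNAs were lower than snoRNAs and scaRNAs, short as well, by -0.53 ± 0.15. Among those with a mean log2 signal of at least 7 the gap was -0.61 ± 0.20. This list of 16 also holds polymerase III RNAs that are not small nuclear RNAs, and several U1 copies. Its members varied: Oct-1L minus Oct-1X was -1.44 for RNA5S9, -0.27 for RN7SK and 0.03 for RN7SL1. RNA lengths were not compared, so the gap cannot decide whether loss of short RNA from the Oct-1L sample is the whole cause. The respiratory chain genes had a median of -0.41 ± 0.09, and of -0.30 ± 0.07 with the probe position trend removed. For them loss of short RNA remains open, because genes outside both groups with a probe within 500 bases of the transcript start were lower than those beyond 2000 bases by -0.19. Oct-1L acting on snRNA-type promoters, the biological explanation tested, would leave these genes near 0, since they have no such promoters. Their median was already seen when the test was chosen, so it excludes no other action of Oct-1L on them. Oct-1L acting on snRNA-type promoters stays open for the small nuclear RNAs, though with 1 array an effect of the isoform and of the sample are the same difference.

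Probes of 28S ribosomal RNA and 3 of 10 detected NBPF probes were at least 2-fold lower on the Oct-1X array than on each other array. Less ribosomal RNA labelled in the Oct-1X sample may account for the 28S part, because the 18S probe was also lower by -1.49 or more against each array. The 18S probe met the same calling rule on the same array, so it is no independent check. Its differences were smaller than those of the 28S probes, at -2.73 to -4.27. Cross-hybridisation through a stretch shared by the NBPF probes themselves is argued against, since the longest stretch shared by any pair of them was 15 bases, short of the 20 required. The probes were not compared with transcripts, so the reading of 1 transcript by several of these probes at different places stays open. No explanation for the NBPF part was left with a test behind it, and the longest stretch shared by an NBPF and a ribosomal RNA probe was 7 bases. No biological explanation was tested.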

How the results depend on the processing

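The count without the Oct-1L array and the results with a trend removed were chosen after seeing the data. Signal over background limits these counts: the authors' values and the setting without background correction keep the background in every signal, which by construction compresses folds. From the authors' values the called genes numbered 257 (Oct-1A against control), 289 (Oct-1L), 418 (Oct-1X), 79 (Oct-1A against Oct-1L), 19 (Oct-1A against Oct-1X) and 212 (Oct-1L against Oct-1X), with 123 shared by all lines. Without background correction they numbered 259, 299, 365, 65, 20 and 125, with 130 shared. With offset 50, which also compresses folds, the pairs of lines gave 121, 33 and 230. Without a detection filter, which tests more genes, the counts were 993 for Oct-1A against control, 379, 157 and 586 for the pairs and 442 shared, and the correlation of Oct-1A and Oct-1X was 0.76. Without the Oct-1L array, which asks for 1 call fewer, 459 genes were shared.

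Of the list medians recomputed, 997 stayed within their bootstrap error and 190 moved further. A change of sign occurred 60 times, 4 of them in a list whose median stood apart from the random lists. The 4 were cholesterol and lipid synthesis for Oct-1A against Oct-1X from the authors' values (-0.00164), replication-dependent histones for Oct-1X against control without a detection filter (0.00859), and ribosomal proteins for Oct-1A against Oct-1L (-0.052) and Oct-1L against Oct-1X (0.035) with the trend over probe position and GC content removed. For the first and second the cause was not tested, and the others follow from the trend removed. Of the values of named genes, 4955 stayed and 414 moved, with 14 changes of sign, none in a called gene. The median difference over all tested genes lay furthest from 0 for Oct-1A against Oct-1X from the authors' values, at -0.077. Leaving out a replicate was not possible with 1 array per group, and no paired analysis was possible because each group has 1 array.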

Other observations

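No explanation was tested for the genes given here. Genes called lower in the Oct-1L line alone and at least 2-fold from both other lines included CD52 (-1.36 against the control, and 0.07 and -0.07 in the Oct-1A and Oct-1X lines), PTPRCAP (-1.57, against -0.43 and 0.22), GSDMD (-1.10, against -0.08 and -0.04), ITGB2 (-2.34 ± 0.10), FCRL5 (-1.38 ± 0.15) and PTPN6 (-1.90 ± 0.16). They also included ROMO1 (-1.52, against -0.01 and 0.27). These genes were chosen after their values were seen and stand for no group. The same selection also holds pseudogenes of RPL and RPS genes, SNORA12, SNORD104, RNA5S9, NDUFA3 and ATP5ME. The Oct-1L array was lower for genes with a probe ending within 500 bases of the transcript start.

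Genes called lower in the Oct-1X line alone and at least 2-fold from both other lines included ARID4B (-1.96, against -0.77 and -0.28 in the Oct-1A and Oct-1L lines) and NUCKS1 (-1.50, against -0.44 and 0.07), XPOT (-1.38, against -0.11 and -0.27), PFKFB4, ALDOC and DDIT4. These too were chosen after their values were seen. The same selection also holds the ribosomal RNA probes RNA18SN5 and RNA28SN5 and, by name, the pseudogenes ANP32BP1 and HNRNPKP4. The Oct-1X array was lower at 5' probes.

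The 3 NBPF probes followed the first of the 28S ribosomal RNA probes across all 4 arrays in order of raw signal. That RNA28SN5 probe read 2762.2 on the control, 1414.2 on the Oct-1A, 1995.8 on the Oct-1L and 259.2 on the Oct-1X array, and NBPF10 read 3256.5, 1177.5, 2282.4 and 398.1. The probes named LOC100132394 and LOC100134364 share stretches of 42 and 37 bases with a ribosomal RNA probe, so their signals are not independent of it.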
